A study of Mus musculus with 8 samples.

How the data were processed

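Gene expression was measured in mouse medullary thymic epithelial cells (mTECs) on Illumina bead arrays. Per the labels, total RNA of sorted cells was checked on a Bioanalyser, and 200 ng of it was amplified and labelled with biotin. The 8 arrays cover 2 genotypes and 2 subsets, with 2 biological replicates per group: control CD80low, knockout CD80low, control CD80high and knockout CD80high.

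The values used are the deposited intensities on a linear scale, 1 per probe and array, with columns named by sample. The authors had made them comparable across arrays by a method that is not given in the sources used here. Array means lay close together, sorted columns were not identical, and no background had been subtracted: the lowest deposited intensity was 74.1 to 80.5 and the median 105.7 to 110.1. A table of values before normalisation has 16 columns, 8 with signals and 8 with detection p-values. Its columns are named only by slide and position, which no label ties to a sample, so that table was not used here. A bead array has no read depth; the signal over background and the number of arrays set the precision.

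Probes were named with the platform table: 35667 carried 1 gene symbol, 0 carried several, and 10422 had none and were left out of gene counts. An Entrez identifier was given for 28742 probes, of which 28519 were found in the RefSeq table of assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other.

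Intensities were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3, with its parameters estimated from the values of each array and an offset of 16. They were then quantile-normalised over all 8 arrays and log2-transformed. Because the authors had already scaled these values, they were normalised a second time. The plan had been to start from the signal table with its control-based correction and to keep probes with a detection p under 0.05. In place of that p, a probe was tested if its deposited intensity lay above the array's background mode plus 1.645 times the standard deviation of the background, estimated from the values below the mode, in both arrays of at least 1 group. The stricter filter used 2.326 in place of 1.645. This left 23378 probes (50.7%) and 14392 genes, each gene represented by its tested probe with the highest mean over the 8 arrays. A fold change against a group in which neither array lay above this background is given as a lower bound.

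Each comparison came from 1 limma fit with a mean per group and moderated variances (4 residual and 6.05 prior degrees of freedom). The contrasts were knockout against control within each subset and averaged over both, CD80high against CD80low within each genotype, and the difference between the subsets' genotype effects, called the interaction. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes; a change was called at an adjusted p under 0.05. With 2 arrays per group an exact permutation test of a single comparison cannot give a p under 0.333.

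The 33 gene lists name 507 genes, of which 396 were tested. Of these lists, 32 had at least 3 tested members and were compared with all other tested genes by camera of limma, with a preset inter-gene correlation of 0.01, and adjusted over the lists of a contrast. The same test with an estimated correlation was run beside it, and so was fry, which asks only whether the genes of a list move one way on balance. Members were counted as passing over all genes and adjusted over the list alone. For each list mean, an exact permutation test relabelled genotypes within subsets (36 relabelings).

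The contrasts, the 33 lists, the adjusted p threshold, most alternatives and the rule for named genes were chosen before the data were examined. Chosen after that were the background threshold above, a replicate term within subset, leaving out both CD80low arrays of replicate 1, and the mTEC subtype, thyroid and kidney and brush border lists. The rule names Hipk2, Aire, Cd80, Ins2, Gad1 and Fezf2; the 10 largest rises and 10 largest falls of a contrast among called genes whose arrays do not overlap; where fewer than 10 genes passed, the 10 with the smallest p; and up to 4 members per list with the smallest p. Genes named outside this rule are said to be chosen after their values were seen. Replicate numbers are not stated to mark a shared animal or sort, so the comparisons reported first use no replicate term.

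The procedure was tested on simulated data with 14392 genes, 2 arrays per group and 1 spread per gene, that of the fit over all 4 groups. The shift was put into knockout CD80low cells. Of 100 genes shifted by 1 on the log2 scale, 38% were called, and of 100 shifted by 2, 84%, with 4 false calls. In a contrast with no simulated change, 0 genes were called. Both subsets had the same simulated spread, and no deviations were shared by replicate number. In the data the replicates lay further apart in CD80low than in CD80high cells. The shares called and the false calls may therefore not hold for the CD80low contrast. A list of 15 genes shifted by -0.7 gave camera p = 8.22e-18, or 7.79e-04 with an estimated correlation, and 3 of 100 unshifted lists had p under 0.05. The simulated noise was drawn for each gene on its own. These list results therefore cannot show how camera with the preset correlation behaves where the genes of a list vary together. In the data the estimated correlation ran from -0.0333 (Wnt targets) to 0.819 (thymocyte genes), against the preset 0.01. For nervous system genes in CD80low cells it was -0.0328, below the preset, yet the camera p rose from 0.00454 to 0.0403. A call lost with an estimated correlation therefore need not come from genes that vary together.

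The alternatives were no background correction, median scaling, cyclic loess, the deposited intensities on a log2 scale, an offset of 50, no filter, a stricter filter, counting every probe, fitting only the groups compared, a trended robust prior, array weights, replicate terms, an additive model, and leaving out each array in turn. A slide term was not run, since slides are known only for the columns not used here.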

Results

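The arrays measured transcripts of mTECs, the thymic epithelial cells that display tissue-restricted self antigens to developing T cells. The cells came from mice with a knockout of Hipk2, a serine/threonine kinase that acts on p53 among other proteins, restricted to thymic epithelial cells (TECs), and from wild-type controls of the matings. They had been sorted by CD80, a costimulatory molecule that is high on mature mTECs, into CD80low and CD80high cells. Each of the 4 groups had 2 biological replicates. Between 20434 probes (44.3%, knockout CD80low replicate 2) and 22974 probes (49.8%, knockout CD80high replicate 2) of all probes lay above the array background. Across probes, the replicates correlated at r = 0.966 in control CD80low, 0.970 in knockout CD80low, 0.988 in control CD80high and 0.982 in knockout CD80high cells.

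The subsets separated the arrays along the first principal component (81.5% of the variance). The second (7.33%) parted replicate 1 from replicate 2 of the CD80low cells in both genotypes. With it went transcripts of other cells: the mean log2 intensity of thymocyte genes was 8.89 in control and 8.97 in knockout CD80low replicate 1 but 7.02 in both replicate 2 arrays. Erythroid genes stood at 8.63 and 8.22 against 6.36 and 6.78 in the same order. Between genotypes in CD80low cells, with both replicates of each, neither list was called (thymocyte genes, median log2 change 0.10, adjusted p = 0.966, erythroid genes, -0.03, adjusted p = 0.75). This rests on the balance of the replicates: without control CD80low replicate 1 the thymocyte median was 0.74 (adjusted p = 1.29e-06) and the erythroid median 1.10 (0.0367), and without knockout CD80low replicate 2 the thymocyte median was 0.98 (9.12e-06). Without control CD80low replicate 2 the thymocyte median was -0.75 (8.24e-04), and without knockout CD80low replicate 1 it was also -0.75 (1.09e-05).

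The first question was what the loss of Hipk2 changes in CD80low mTECs. Slc13a2, a sodium-coupled transporter of citrate and other dicarboxylates known from kidney and intestine, rose 37.6-fold. Its mean log2 intensity was 5.93 ± 0.12 (SD, n = 2) in controls and 11.16 ± 0.46 (SD, n = 2) in knockouts, a change of 5.23 ± 0.233 (SE, adjusted p = 9.31e-06). The size depends on the background step: the log2 change was 4.19 with no background correction and 4.22 with the deposited values. Markers of thymic tuft cells, chemosensory epithelial cells that produce IL-25, fell as a set: 14 of 14 tested genes were lower, with a median log2 change of -1.16 (adjusted p = 4.18e-25). That call was lost when gene correlation was estimated (adjusted p = 0.226 with an estimated correlation). Skeletal muscle genes, which rare mTECs express, fell by a median of 0.74 on the log2 scale with 14 of 15 lower (adjusted p = 4.33e-16, adjusted p = 0.0762 with an estimated correlation).

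In this fit no tuft or muscle gene passed on its own over all genes. Adjusted over the list alone, 13 tuft genes and 11 muscle genes were lower. Among tuft markers the actin-binding protein Avil changed by -1.81 ± 0.256 (SE, log2, adjusted p = 0.0714), the cytokine Il25 by -1.79 ± 0.334 (0.142), the G protein subunit Gnb3 by -1.67 ± 0.306 (0.142) and Sh2d6 by -1.69 ± 0.329 (0.17), none past the threshold. The tuft list averaged 9.57 and 8.86 in the control arrays and 8.00 and 7.94 in the knockout arrays, and the thymocyte genes were higher in the first of each pair. Of the muscle genes, troponin C Tnnc2 differed by -1.59 ± 0.282, myosin heavy chain Myh1 by -1.22 ± 0.224, Mylpf by -0.91 ± 0.198 and actin Acta1 by -0.87 ± 0.187, again not past it (adjusted p = 0.142, 0.142, 0.212 and 0.212). Avil passed with a trended robust prior (adjusted p = 0.0162), with no filter (0.0482) and in other settings, and Gnb3 and Tnnc2 each passed in 1 setting. Leaving out control CD80low replicate 2 left only the control array with the higher tuft mean. The log2 changes were then -2.168 for Avil, -2.266 for Sh2d6, -2.325 for Il25, -2.265 for Trpm5 and -1.76 for Gnat3. Trpm5 and Gnat3 are named here after their values were seen. Over all settings the tuft median ran from -1.47 to -0.91. Muscle was the 1 list also called by fry (adjusted p = 0.0157).

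Cornified keratinocyte genes were lower in 17 of 19 cases (median -0.47, adjusted p = 1.74e-07, adjusted p = 0.343 with an estimated correlation), and 6 passed adjusted over the list alone. Their median ran from -0.83 to -0.24 over the settings. These genes averaged 7.14 and 7.47 in control and 6.48 and 7.09 in knockout CD80low arrays. Sprr2d differed by -1.21, involucrin (Ivl) by -0.88 and Dmkn by -0.87, while Lce1a1, at background in knockouts, was at least 1.63-fold lower; none passed over all genes. Cell cycle genes were higher in 19 of 20 cases (median 0.47, adjusted p = 1.2e-08, adjusted p = 0.383 with an estimated correlation), with Rrm2 at 0.87, the kinase Cdk1 at 0.74, Plk1 at 0.69 and Top2a at 0.60. None of them passed, even adjusted over the list alone. The list averaged 7.41 and 7.48 in control and 7.79 and 8.00 in knockout arrays.

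Smaller shifts were called for 5 further lists, each lost with an estimated correlation and when single arrays were left out. Epithelial identity genes were lower in 11 of 13 cases (median -0.17, adjusted p = 0.00491, adjusted p = 0.395 with an estimated correlation, 0.103 without knockout CD80low replicate 1). The tight junction gene Cldn3 was at -0.96 and the transcription factor Elf3 at -0.95, and these 2 passed adjusted over the list alone. Nervous system genes had a median of -0.20 (adjusted p = 0.0208, adjusted p = 0.343 with an estimated correlation). That adjusted p was 0.0568 without control CD80low replicate 2 and 0.07 without knockout CD80low replicate 1. The myelin gene Mag, at -1.58, was the 1 member that passed adjusted over the list alone.

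Pancreas genes had a median of -0.21 (adjusted p = 0.0245, adjusted p = 0.675 with an estimated correlation). Their members went both ways: somatostatin (Sst) stood at -1.96 and glucagon (Gcg) at 1.18, and these passed adjusted over the list alone. The pancreas call ended without control CD80low replicate 1 (0.0951), control CD80low replicate 2 (0.143) or knockout CD80low replicate 1 (0.523), and with the deposited values (0.149), no background correction (0.136), an offset of 50 (0.0705) or no filter (0.0556). Cortical TEC genes were higher in 10 of 10 cases (median 0.35, adjusted p = 0.0103, adjusted p = 0.643 with an estimated correlation), among them the endocytic receptor Ly75 at 0.82. Without control CD80low replicate 2 the cortical adjusted p was 0.268, and without knockout CD80low replicate 1 the direction turned (0.957). Myeloid and dendritic cell genes were higher in 10 of 13 cases (median 0.15, adjusted p = 0.0211, adjusted p = 0.343 with an estimated correlation), led by lysozyme Lyz2 at 1.07, the 1 gene that passed adjusted over the list alone. The myeloid call ended with no filter (0.211) or without 1 of 5 arrays: control CD80low replicate 1 (0.133) or 2 (0.0568), knockout CD80low replicate 2 (0.766), control CD80high replicate 1 (0.0722) or knockout CD80high replicate 1 (0.0825).

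Aire-dependent genes were not called in CD80low knockouts, and mature mTEC genes missed the threshold. The Aire-dependent tissue-restricted genes had a median log2 change of -0.02 (mean 0.12, adjusted p = 0.692), mature CD80high mTEC genes 0.14 (adjusted p = 0.0657) and immature mTEC genes 0.07 (adjusted p = 0.673). The mature list was called in 7 of 21 settings, always as higher, among them no background correction (0.0377), the deposited values (0.0444), without control CD80low replicate 2 (0.0121) and without knockout CD80low replicate 1 (0.0184). Its median ran from -0.01 to 0.32 over the settings, and its adjusted p = 0.686 with an estimated correlation. Aire, the transcriptional regulator of self-antigen display, differed by -0.03 ± 0.212 (SE), Cd80 by 0.14 ± 0.329, Fezf2 by -0.34 ± 0.232 and Gad1 by -0.54 ± 0.236. Ins2 was at background in knockouts and at least 1.09-fold lower; none of these passed. p53 targets had a median of 0.05 (adjusted p = 0.601), with Ccng1 at 0.64 and Plk2 at -0.78. The adjusted p was also above the threshold for mTEC chemokines (0.439), NF-kB signalling (0.998), Aire-independent tissue-restricted genes (0.32), liver (0.401), secretory gland (0.315), intestinal (0.0657), testis (0.79) and retina genes (0.315). It was 0.938 for B cell, 0.75 for fibroblast and 0.315 for endothelial genes, 0.239 for Wnt targets, 0.315 for TGF-beta targets, 0.692 for the Hipk family, 0.995 for Aire partner, 0.506 for interferon-stimulated and 0.966 for immediate-early genes. Median and test differed in sign for thymocyte, erythroid, Aire partner and Aire-independent genes.

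**Figure D1:**
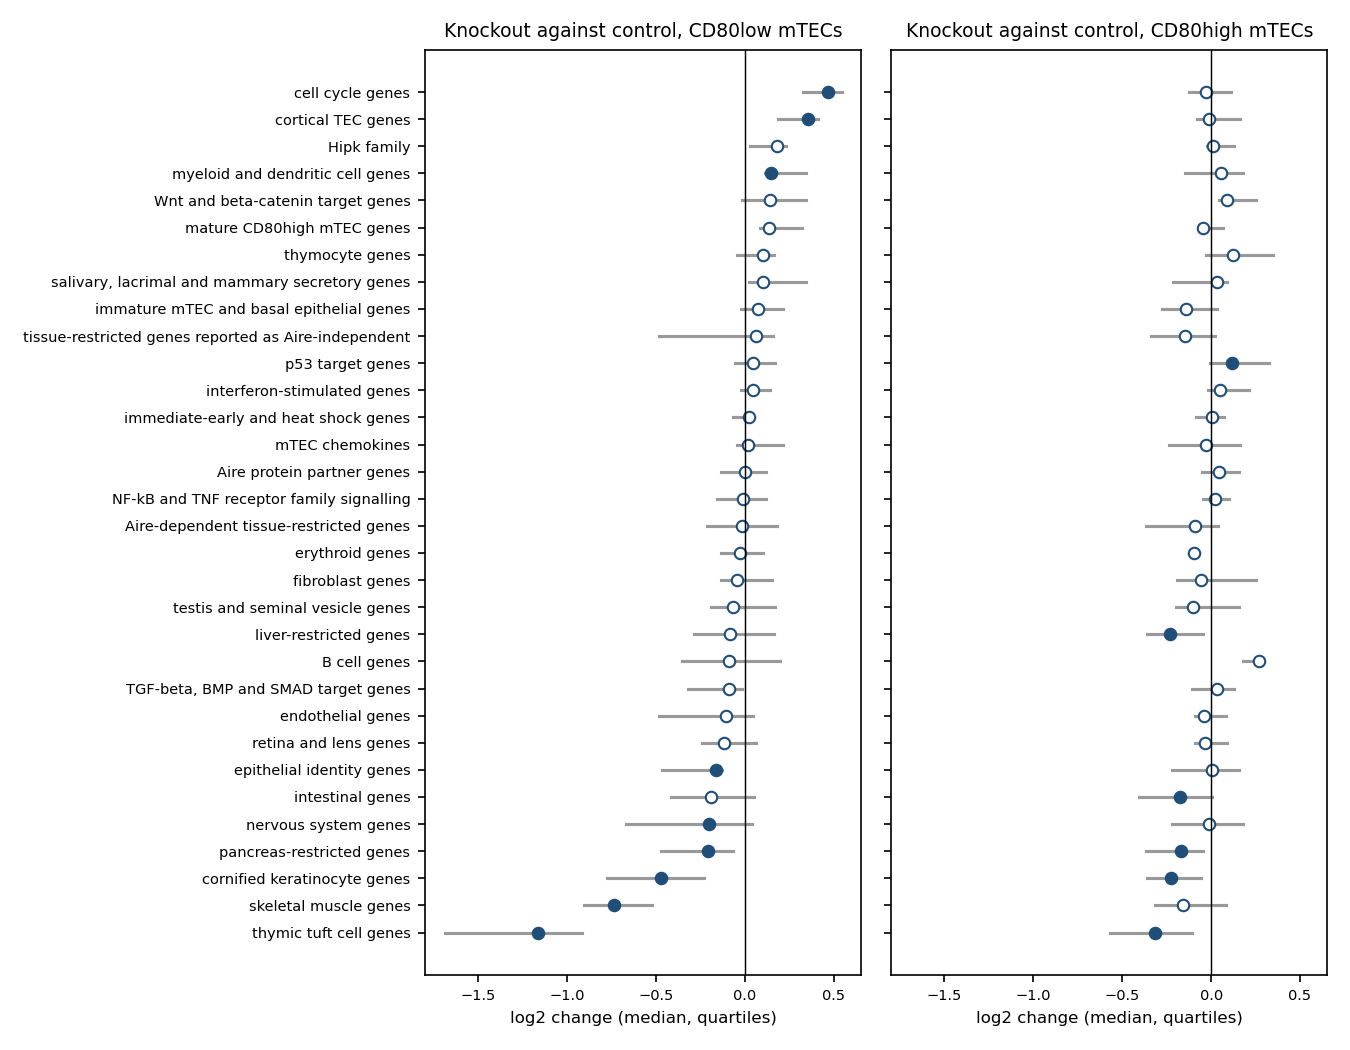
Median log2 change (circle) and quartiles (bar) of the members of each of 32 gene lists, knockout against control, in CD80low (left) and CD80high mTECs (right); filled circles have a camera adjusted p under 0.05 at the preset correlation of 0.01, and none of them does with an estimated correlation. The tuft list lies lowest in both subsets, at -1.16 and -0.31.

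By limma, Slc13a2 was the 1 gene of 14392 called in CD80low cells. At an unadjusted p under 0.05 there were 914 genes, 319 higher and 595 lower, where chance gives 719.6. The fit shared 1 spread per gene over all 4 groups, though replicates lay further apart in CD80low cells. The SD of their log2 difference was 0.515 in control and 0.488 in knockout CD80low cells, against 0.303 and 0.367 in CD80high cells. P-values may therefore run low here and high in CD80high cells, so the counts of the 2 subsets are not comparable. Fitted with only the CD80low arrays, Slc13a2 had an adjusted p of 0.0122. The next 9 by p, none past the threshold, were Clic6 (-1.47), Hamp2 (-1.93), Mag, Krt79 (-1.36), Avil and Neurl (-1.43), each with adjusted p = 0.0714, then Tspan8 (-1.45, 0.0809), Bmx (-1.52, 0.11) and D530004J12Rik (-1.38, 0.118). The count rose to 24 without control CD80low replicate 2, to 9 without knockout CD80low replicate 2 and to 3 without knockout CD80low replicate 1. Among the alternatives without a replicate term, it was 11 with a trended robust prior, 5 with no filter, 4 with the deposited values and 2 with an offset of 50.

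In CD80high mTECs, the comparison asked what Hipk2 loss changes in mature cells. Slc13a2 rose 88.1-fold, from 7.05 ± 0.0262 (SD, n = 2) to 13.51 ± 0.053 (SD, n = 2), a log2 change of 6.46 ± 0.233 (SE, adjusted p = 1.15e-06), or 5.87 with no background correction and 5.85 with the deposited values. The list of p53 targets was higher (median 0.12, 13 of 19 genes, adjusted p = 6.66e-04, adjusted p = 0.241 with an estimated correlation). Its members Phlda3 (0.83 ± 0.187 SE), the cell cycle inhibitor Cdkn1a (0.70 ± 0.184), Ccng1 (0.69 ± 0.21) and Zmat3 (0.66 ± 0.256) each had adjusted p = 1 over all genes, and 2 genes of the list passed adjusted over the list alone. Tuft genes were lower in 13 of 14 cases (median -0.31, adjusted p = 0.00126, adjusted p = 0.611 with an estimated correlation), with Gnat3 at -0.70, Trpm5 at -0.72 and Avil at -0.61 but Dclk1 at 0.43. No tuft gene passed adjusted over the list alone.

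Of the lists of peripheral tissue genes, 4 were also lower in CD80high knockouts and the others were not called. The intestinal, pancreas and liver lists share genes with the Aire-dependent list, for example Reg3g, Ins2 and Mup2. The liver and cornified lists share genes with the Aire-independent list, for example Apoc3 and Krt10. Results of lists that share genes are not separate from each other. Intestinal genes had a median of -0.17 (adjusted p = 0.00149, adjusted p = 0.241 with an estimated correlation), with the antimicrobial lectins Reg3b at -0.79 and Reg3g at -0.61. Pancreas genes had a median of -0.17 (adjusted p = 0.00669), cornified keratinocyte genes -0.22 (adjusted p = 0.00674) and liver genes -0.23 (adjusted p = 0.0453), and each of these 3 had adjusted p = 0.611 with an estimated correlation. Sycn stood at -0.54 and Reg1 at -0.41, keratin Krt10 at -0.58, haptoglobin (Hp) at -0.69 and Apoc3 at -0.52; none passed. Adjusted over the list alone, 0 genes of these 4 lists were called. Aire-dependent tissue-restricted genes had a median of -0.09 (adjusted p = 0.119). They were called as lower in 5 of 21 settings, among them no filter (0.0117), without knockout CD80high replicate 1 (median -0.35, 0.00534) and without knockout CD80low replicate 1 (0.0423), and the median was 0.08 (0.937) without knockout CD80high replicate 2. Aire differed by 0.06 ± 0.212 (SE), Cd80 by 0.11 ± 0.329, Fezf2 by -0.07 ± 0.232, Gad1 by -0.11 ± 0.236 and Ins2 by -0.30 ± 0.222. Muscle genes (median -0.16, adjusted p = 0.0967) and cell cycle genes (median -0.03, adjusted p = 0.906) were not called. Nor were nervous system (-0.01, 0.867), retina (-0.03, 0.924), testis (-0.10, 0.865), secretory gland (0.03, 0.906) and Aire-independent genes (-0.15, 0.31). For the other 18 lists the adjusted p was 0.234 or more.

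All 6 list calls in CD80high cells ended without knockout CD80high replicate 2 (0 lists): p53 0.147, tuft 0.0618, intestinal 0.0618, pancreas 0.769, cornified 0.156 and liver 0.456. Without control CD80high replicate 1 the adjusted p was 0.236 for pancreas and 0.0622 for tuft genes, and without control CD80high replicate 2 it was 0.239 for intestinal, 0.485 for cornified and 0.528 for liver genes; the liver call also ended in 5 processing alternatives (0.0502 to 0.127). By limma, Slc13a2 was the 1 gene called, with 218 genes at an unadjusted p under 0.05 where chance gives 719.6. Because the spread shared with the CD80low arrays is wide for these arrays, that count does not compare the subsets. The bile salt transporter Abcb11 came next (2.01 ± 0.296 SE, adjusted p = 0.341). Then, each with adjusted p = 1, followed 1110014O20Rik (-1.46), the cell cycle inhibitor Cdkn1c (-0.89), Clca3b (-1.07), Phlda3, Spock3 (-0.99), Cyp2g1 (-1.25), Fcer1g (0.86) and Ajap1 (-0.83).

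**Figure D2:**
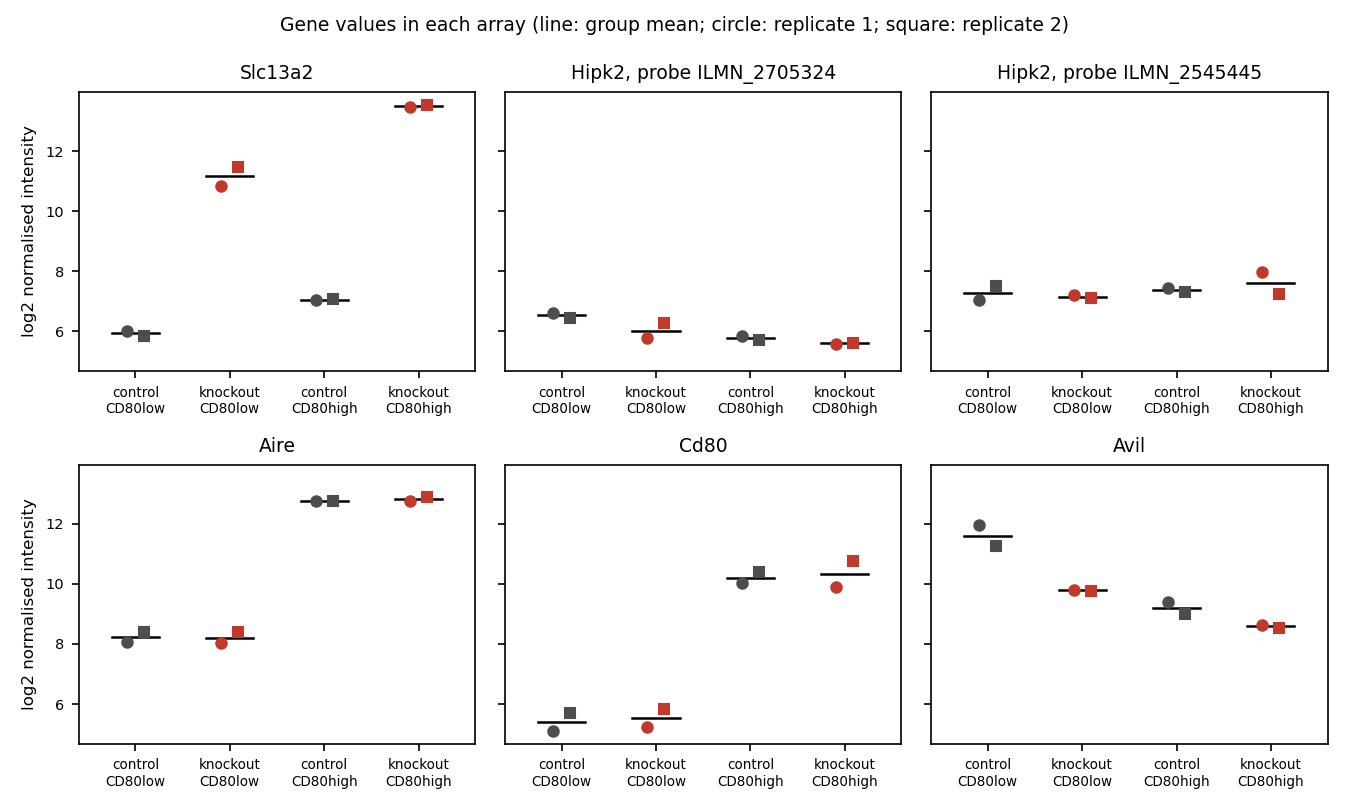
Log2 normalised intensity of Slc13a2, both tested Hipk2 probes, Aire, Cd80 and Avil in each array (grey, control, red, knockout, circle, replicate 1, square, replicate 2, line, mean of 2 arrays). Slc13a2 lies at 10.84 or more in the 4 knockout arrays and at 7.07 or less in the 4 control arrays.

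Averaged over both subsets, 4 knockout against 4 control arrays, Slc13a2 rose 57.6-fold (log2 change 5.85 ± 0.165 SE, adjusted p = 9.88e-08). The log2 change was 5.03 with no background correction and 5.04 with the deposited values. Slc13a2 was the 1 gene called by limma. At an unadjusted p under 0.05 there were 715 genes, of which 512 were lower, where chance gives 719.6. The next 9 genes shared an adjusted p of 0.0888 and did not pass: Abcb11 at 1.47 and, on the negative side, Alox5ap (-1.31), Hamp2 (-1.25), Avil (-1.21), Bmx (-1.15), Mag (-1.12), Tspan8 (-1.07), Clic6 (-0.96) and Cdkn1c (-0.88). Alox5ap acts in leukotriene synthesis, an activity of tuft cells. Tuft genes were lower in 14 of 14 cases (median -0.74, adjusted p = 3.79e-23, adjusted p = 0.173 with an estimated correlation) and muscle genes in 15 of 15 (median -0.42, adjusted p = 8.89e-14, adjusted p = 0.102 with an estimated correlation). Camera called 12 lists in all. Cornified (median -0.40, adjusted p = 1.61e-08), intestinal (-0.21, 6.99e-04), pancreas (-0.22, 6.99e-04), epithelial identity (-0.06, 0.0157), nervous system (-0.08, 0.0427) and liver genes (-0.12, 0.0462) were lower. Cell cycle (0.22, 3.08e-05), myeloid (0.15, 0.0111), p53 target (0.06, 0.0127) and cortical TEC genes (0.15, 0.0336) were higher, and each of these 10 had an adjusted p of 0.173 or more with an estimated correlation. Aire differed by 0.01, Cd80 by 0.12, Fezf2 by -0.20, Gad1 by -0.32 and the brighter Hipk2 probe by 0.06, none past the threshold. Ins2, at background in CD80low knockouts, did not pass either and is given no averaged change. The averaged change of the other Hipk2 probe, ILMN_2705324, was -0.35 ± 0.15 (SE, adjusted p = 1 over all tested probes).

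The exact permutation test of the averaged list means gave 0.0556, the smallest p that 36 relabelings allow, for tuft, muscle, cornified, intestinal and Wnt target genes. The averaged count of called genes was 16 with a trended robust prior, 8 with no filter, 4 with the deposited values, 3 with no background correction and 3 with an offset of 50. It was 15 without control CD80low replicate 2, 6 without knockout CD80low replicate 2 and 2 without knockout CD80low replicate 1.

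The averaged calls of tuft, muscle, cornified and intestinal genes held whichever single array was left out, and each of the other 8 ended without at least 1. Processing ended some of them too. By camera, the liver call ended with median scaling (adjusted p = 0.0557), cyclic loess (0.0566), no filter (0.197) and a trended robust prior (0.0565). The nervous system call ended with cyclic loess (0.0563) and the additive model (0.0652). With no filter the myeloid (0.102) and cortical TEC calls (0.0878) ended. Without knockout CD80high replicate 2 only 6 lists were called, and the adjusted p was 0.0872 for pancreas, 0.209 for liver, 0.11 for nervous system, 0.453 for cortical TEC, 0.0559 for myeloid and 0.0872 for p53 target genes. Without control CD80low replicate 2 it was 0.0562 for epithelial identity, 0.0562 for nervous system, 0.298 for liver and 0.298 for cortical TEC genes. Without knockout CD80low replicate 1 it was 0.119 for epithelial identity, 0.0523 for pancreas, 0.101 for nervous system and 0.89 for cortical TEC genes, and without replicate 2 of that group 0.558 for liver, 0.353 for myeloid and 0.196 for p53 target genes. Without control CD80high replicate 1 it was 0.0869 for nervous system, 0.105 for cortical TEC and 0.154 for myeloid genes, and without replicate 2 of that group 0.294 for epithelial identity, 0.294 for liver and 0.0548 for cell cycle genes. Nervous system genes also lost their call without control CD80low replicate 1 (0.062), and epithelial identity genes without knockout CD80high replicate 1 (0.126).

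**Figure D3:**
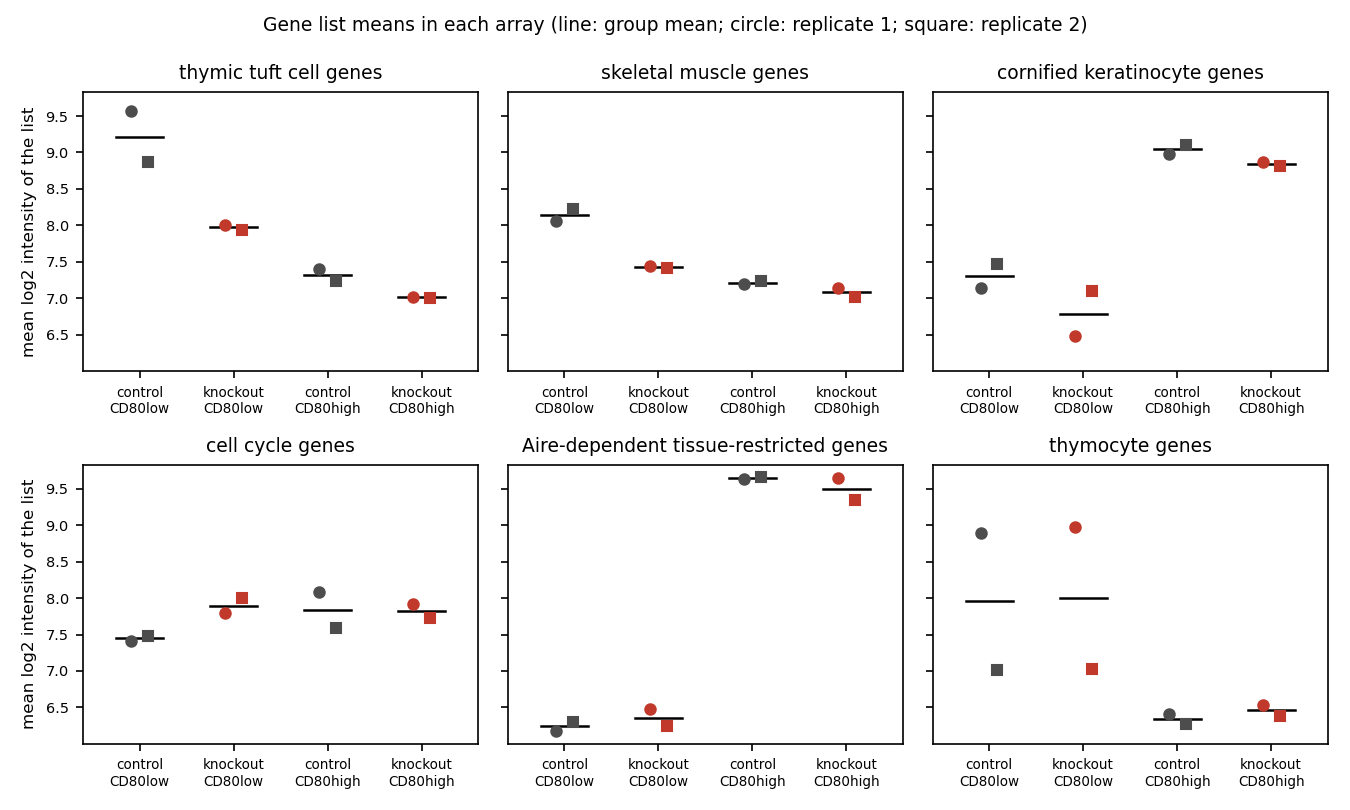
Mean log2 intensity of the tested members of 6 gene lists in each array (grey, control, red, knockout, circle, replicate 1, square, replicate 2, line, mean of 2 arrays). Tuft genes average 9.57 and 8.86 in control and 8.00 and 7.94 in knockout CD80low arrays; thymocyte genes part the CD80low replicates in both genotypes.

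The interaction asked whether the genotype effect differed between subsets. For tuft genes camera called a difference: the log2 change was less negative, or positive, in CD80high cells for 14 of 14 genes. The median difference was 0.93 (adjusted p = 1.3e-14, adjusted p = 0.542 with an estimated correlation), and 6 passed adjusted over the list alone. For muscle genes the median difference was 0.59 (13 of 15 genes, adjusted p = 5.92e-10, adjusted p = 0.188 with an estimated correlation), with 2 passing adjusted over the list alone. Both lists were dimmer in CD80high than in CD80low controls. Tuft genes averaged 7.31 against 9.215 and muscle genes 7.21 against 8.145. That left them less room to fall in CD80high cells, and its part in the difference was not tested. Cell cycle genes had a median of -0.50 (19 of 20 negative, adjusted p = 7.61e-07, adjusted p = 0.722 with an estimated correlation). Their call ended without control CD80high replicate 1. Over the settings the median ran from -0.81 to -0.18, and the list averaged 8.08 and 7.59 in the control CD80high arrays. Largest by p were Dclk1, a tuft cell kinase (1.45 ± 0.288 SE), Cacng4 (1.26), Krt79 (1.22), R3hcc1l (1.19), Atp8b2 (-1.20), D530004J12Rik (1.33), Pnliprp2 (-1.17), Pp2d1 (-1.07), Stmn4 (1.17) and Pcbd1 (1.31), each with adjusted p = 1. Slc13a2 differed by 1.23 ± 0.33 (SE, unadjusted p = 0.00392, adjusted p = 1). For Aire the difference was 0.09, for Cd80 -0.02, for Fezf2 0.27, for Gad1 0.44 and for the Hipk2 probes 0.36 and 0.33, none past the threshold. Ins2, again for its background level, is given no difference and did not pass.

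Cornified (median 0.22, adjusted p = 0.0255, adjusted p = 0.95 with an estimated correlation) and epithelial identity genes (median 0.19, adjusted p = 0.0463, adjusted p = 0.865 with an estimated correlation) completed the 5 lists called. The cornified call ended without control CD80low replicate 2 (0.382), knockout CD80low replicate 1 (0.879), control CD80high replicate 1 (0.105), knockout CD80high replicate 1 (0.0816) or 2 (0.138), and with no background correction (0.107). The epithelial call ended without either control CD80low replicate (0.0721 and 0.0641), knockout CD80low replicate 1 (0.262), control CD80high replicate 1 (0.356) or knockout CD80high replicate 2 (0.538). By limma, 0 genes were called, and 435 had an unadjusted p under 0.05 where chance gives 719.6; fry called 0 lists. The count was 1 without control CD80low replicate 2, 1 without knockout CD80low replicate 1 and 3 without knockout CD80low replicate 2.

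Hipk2 itself had 2 tested probes. By limma, ILMN_2705324 stood at 6.54 ± 0.112 (SD, n = 2) in control and 6.03 ± 0.333 (SD, n = 2) in knockout CD80low cells, a log2 change of -0.51 ± 0.212 (SE, unadjusted p = 0.0361, adjusted p = 0.705 over all tested probes), and differed by -0.19 ± 0.212 in CD80high cells. ILMN_2545445, the brighter probe, differed by -0.12 ± 0.267 and 0.24 ± 0.267. The sign of ILMN_2545445 turned without control CD80low replicate 2 (0.13) and, in CD80high cells, without knockout CD80high replicate 1 (-0.12). The position of either probe relative to the deleted part of the gene is not given in the sources used here, so neither value checks the genotype.

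The genotype effects of the 2 subsets correlated weakly across genes (Pearson r = 0.18, Spearman 0.093, r = 0.148 without Slc13a2). Regrouping the arrays of each subset by replicate number in place of genotype gave r = 0.137, so a value of this size also arises without genotype. Replicate number is, however, a structure that the arrays of both genotypes share. All other regroupings gave absolute r of 0.00318 to 0.061. The CD80high against CD80low effects of controls and knockouts correlated at r = 0.958 (Spearman 0.92). Genes are not independent replicates, so no p is given.

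The subset comparison in controls shows how far the 2 sorted subsets differ. It may mix maturation with cell content, since thymocyte and fibroblast genes were lower in CD80high cells and myeloid genes higher. The largest rises in CD80high cells by the rule for named genes were those of the milk protein Csn2 by 6.45 ± 0.49 (log2, SE), the pepsinogen Pgc by 5.89 ± 0.29, Fabp9 by 5.82, Vmo1 by 5.57, the apolipoprotein Apoa4 by 5.54, Klk4 by 5.51, the neuropeptide Gal 45.4-fold, the gut hormone Pyy by 5.45, Calb2 by 5.43 and Serpinb12 by 5.32. Parathyroid hormone, Pth, had the largest fall (-5.34 ± 0.373), followed by Scarf2 (-4.76), the matrix protein Mgp (-4.53), Igkv1-110 (-4.35 ± 1.42), the muscle genes Myl1 (-4.33) and Acta1 (-4.28), Ltbp4 (-4.28), Frmd6 (-4.27), Col6a2 (-4.22) and Sult5a1 (-4.15). Aire rose by 4.51 ± 0.212, Cd80 by 4.82 ± 0.329, Gad1 by 3.14, Ins2 by 3.00 and Fezf2 by 1.82. The Hipk2 probes disagreed: ILMN_2705324 fell by 0.76 ± 0.212 (SE, adjusted p = 0.0181 over all tested probes), while the brighter ILMN_2545445 differed by 0.10 (adjusted p = 0.798). Limma called 5916 genes, 3183 higher and 2733 lower, of which 2139 and 1420 changed more than 2-fold.

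By list, 15 of 16 Aire-dependent genes rose (median 3.51, adjusted p = 3.67e-09, adjusted p = 0.129 with an estimated correlation), as did 14 of 16 intestinal genes (median 3.07, adjusted p = 1.26e-09, 0.0669 with an estimated correlation) and 15 of 16 pancreas genes (median 2.55, adjusted p = 2.44e-08, 0.157 with an estimated correlation). Rises were also called for 8 of 10 Aire-independent genes (1 fell, median 2.87), 9 of 12 secretory gland genes (3.14), 12 of 15 liver genes (2.03), 15 of 19 cornified genes (1.78), 10 of 11 retina genes (1.12), 8 of 12 nervous system genes (2 fell, 1.06) and 4 of 11 testis genes (0.60); their adjusted p with an estimated correlation was 0.139 to 0.194. Of 15 mature mTEC genes, 12 rose (median 1.26, adjusted p = 3.08e-06, adjusted p = 0.194 with an estimated correlation), among them the costimulatory Cd86 (4.09) and Cd40 (2.90). Chemokines (8 of 11, with 1 lower, 1.32), led by Ccl20 (3.70) and Ccl5 (3.68), and NF-kB signalling genes (10 of 17, with 4 lower, 0.94), led by Tnfrsf11b (4.06) and Traf1 (3.13), rose too (0.151 and 0.249 with an estimated correlation).

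Myeloid genes rose in 9 of 13 cases (median 1.40, adjusted p = 0.139 with an estimated correlation), among them Fcer1g (3.56) and Lyz2 (3.49), as did 3 of 4 B cell genes (1.68, adjusted p = 0.195 with an estimated correlation). Tuft genes were lower in CD80high cells in 11 of 14 cases (median -2.32, adjusted p = 3.33e-06, adjusted p = 0.195 with an estimated correlation), for example Sh2d6 (-3.23) and Gnat3 (-2.92). Interferon-stimulated genes fell in 11 of 17 cases (median -1.87, adjusted p = 1.21e-06, adjusted p = 0.151 with an estimated correlation), led by Mx2 (-3.26) and Ifit3 (-3.22), and TGF-beta targets in 8 of 10 (-1.68, adjusted p = 0.194 with an estimated correlation), led by Id1 (-3.59). Immature mTEC genes fell in 8 of 12 cases and rose in 2 (median -1.52, adjusted p = 0.229 with an estimated correlation), with Lifr at -3.69 and keratin Krt5 at -2.62. Immediate-early genes (6 of 13 lower, -0.90), muscle genes (8 of 15 lower and 3 higher, -1.02) and fibroblast genes (7 of 13 lower and 2 higher, -0.68) were lower as well (0.194, 0.194 and 0.195 with an estimated correlation). Thymocyte genes were lower in 4 of 17 cases (median -1.55, adjusted p = 0.00237, adjusted p = 0.48 with an estimated correlation).

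The adjusted p of the remaining lists was above the threshold: epithelial identity (0.411), cortical TEC (0.0708), endothelial (0.874), erythroid (0.0814), p53 target (0.481), Wnt target (0.0708), Hipk family (0.937), Aire partner (0.0708) and cell cycle genes (0.134). Sex-linked genes, with 2 tested members, were too few for a list test.

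In knockouts the same subset comparison asked whether the subsets differ in the same way without Hipk2. Csn2 (6.39 ± 0.49, log2, SE), Pgc (6.20), Vmo1 (5.56), Hal (5.47), Serpinb12 (5.39), Apoa4 (5.32), Gal (5.28), Saa3 (5.26) and Idi2 (5.22) rose most, and Calb2, at background in CD80low knockouts, was at least 29.9-fold higher. Pth (-4.91 ± 0.373), Scarf2 (-4.75), Mgp (-4.62), Myl9 (-4.37), Frmd6 (-4.34), Prelp (-4.19), Igfbp4 (-4.04), Ptn (-3.98) and Sult5a1 (-3.92) fell most, and an immunoglobulin kappa variable gene, at background in CD80high knockouts, was at least 14.4-fold lower. Aire rose by 4.60 ± 0.212, Cd80 by 4.80, Gad1 by 3.58, Fezf2 by 2.09 and Ins2 at least 7.06-fold. The Hipk2 probes again went opposite ways, ILMN_2545445 by 0.46 (adjusted p = 0.197) and ILMN_2705324 by -0.43 ± 0.212 (SE, adjusted p = 0.14 over all tested probes), neither past the threshold. Limma called 5796 genes, 3143 higher and 2653 lower. Of these, 2674 were higher and 2099 lower in both genotypes, and 1 changed in opposite directions. Independence would give 695.1 and 503.8. Both contrasts compare the same 2 kinds of sorted cells, so an excess over independence was certain beforehand and tests nothing about Hipk2.

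Camera called 22 lists in knockouts and 23 in controls, 0 of them with an estimated correlation (smallest adjusted p = 0.065 and 0.0669), while fry called 28 and 27. Aire-dependent genes rose in 14 of 16 cases in knockouts (median 3.19, adjusted p = 7.61e-09, adjusted p = 0.12 with an estimated correlation). Tuft genes were lower in CD80high knockouts in 9 of 14 cases and higher in 2 (adjusted p = 0.00438, adjusted p = 0.378 with an estimated correlation), and muscle genes were not called (median -0.42, adjusted p = 0.254).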

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

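The 3 tests that weigh explanations of the tuft pattern here were chosen after the result was seen. An exact permutation p of the tuft list mean (0.0556), the count of lower tuft genes (14 of 14) and the number of other mTEC subtype lists called in CD80low knockouts (1 of 6) had also been tried as tests and were dropped once their values were known.

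The genotype effect differed between CD80low and CD80high cells for 5 gene lists. Tuft cell genes (adjusted p = 1.3e-14) and muscle genes (5.92e-10) were lower in knockouts mainly in CD80low cells, and cell cycle genes (7.61e-07) were higher there. Tuft and muscle genes were also dimmer in CD80high than in CD80low controls, which left them less room to fall in CD80high cells. For cornified keratinocyte genes (0.0255) and epithelial identity genes (0.0463) the difference was smaller. All 5 calls are lost with an estimated correlation, where the smallest adjusted p is 0.188.

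Lower tuft cell genes in knockout CD80low cells could come from CD80high cells in that sort, in which these genes are dim, but 68.8% of the RNA would have to be of that kind. The Aire-dependent genes would then have risen by a median of 2.90, and the observed changes lay below the expected ones by a median difference of -2.82. Dilution by other cells would lower immature mTEC genes as well, yet the first quartile of their changes lay 1.14 above the tuft median. Under 5 scaling and background settings the tuft median was at most -0.95, which argues against these steps as the source. All 5 start from the deposited values, so the scaling that the authors had already done was not tested. An effect of Hipk2 loss on tuft-type mTECs or on their share of the CD80low cells stays open and untested, as does a difference between the few animals used. So does an effect of the driver construct that restricts the knockout to TECs, since the labels name no driver. The same limit holds for the other comparisons of knockout with control.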

How the results depend on the processing

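Slc13a2 was called in knockouts of both subsets in each setting that tests them apart, and averaged in the additive model, while the number of other genes varied. In CD80low cells, where 1 gene was called, the count was 4 with the deposited values, 2 with an offset of 50, 5 with no filter on dim probes and 11 with a trended robust prior. With replicate number as a term over all arrays it was 5, and with the number as a term within each subset, an alternative added after the data were seen, it was 32. Those 32 include the tuft genes Avil, Gnb3, Ltc4s and Trpm5 (adjusted p = 0.0238, 0.0238, 0.0355 and 0.0485) and the muscle gene Tnnc2 (0.0238), with Ltc4s and Trpm5 named after their values were seen, and Avil was also among the 5 (0.0475). Without both CD80low arrays of replicate 1, where thymocyte transcripts stood higher, also added afterwards, it was 5. Averaged over both subsets, in the same order, the counts were 4, 3, 8, 16, 6, 18 and 4 in place of 1, and 3 with no background correction. For the interaction, replicate number within subset gave 1 gene and leaving out both of those arrays 3, in place of 0.

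Leaving out 1 array gave 1 to 24 genes in CD80low cells (lowest without control CD80low replicate 1, highest without control CD80low replicate 2), 1 in CD80high cells and 1 to 15 averaged (lowest and highest without the same arrays). It gave 0 to 3 for the interaction (highest without knockout CD80low replicate 2), 4058 to 5909 between the subsets of controls and 4133 to 6000 between those of knockouts. The number of lists called ran from 8 to 10 in CD80low cells, 0 (without knockout CD80high replicate 2) to 9 (without knockout CD80high replicate 1) in CD80high cells, 6 to 13 averaged, 2 to 9 for the interaction, 23 to 26 in controls and 21 to 24 in knockouts. With an estimated correlation camera called 0 lists in all 6 contrasts, and fry called 1 in CD80low cells, 0 in CD80high cells, 1 averaged and 0 for the interaction. Some lists that were not called had calls in other settings: of 21, in CD80low cells, 7 for mature mTEC, 4 for thymocyte, 4 for intestinal, 2 for liver and 1 each for erythroid, endothelial and TGF-beta target genes. In CD80high cells there were 5 for Aire-dependent, 2 for cell cycle, 2 for interferon-stimulated and 1 each for muscle, B cell, immediate-early and Aire-independent genes. For the interaction there were 5 for nervous system, 5 for cortical TEC, 4 for thymocyte, 4 for p53 target, 2 for B cell and 1 each for erythroid, immature and mature mTEC genes. An offset of 50 gave 8 lists for the interaction, and leaving out both CD80low arrays of replicate 1 gave 3. The cortical TEC list turned direction without knockout CD80low replicate 1 (adjusted p = 0.957) and had an adjusted p of 8.95e-06 without knockout CD80low replicate 2. A group left with 1 array takes its variance from the other groups.

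The Hipk2 probe ILMN_2705324 ran from -0.75 to -0.27 in CD80low cells when 1 array was left out and was -0.20 without both CD80low arrays of replicate 1. In CD80high cells it ran from -0.25 to -0.11, and was -0.081 with no background correction, -0.10 with the deposited values and -0.11 with an offset of 50. ILMN_2545445 ran from -0.36 to 0.13 in CD80low cells, with -0.39 without both arrays of replicate 1, and from -0.12 to 0.61 in CD80high cells. The correlation of genotype effects between subsets, without Slc13a2, was 0.188 with no background correction, 0.19 with the deposited values, 0.0902 with no filter and 0.112 without both arrays, and 0.061 to 0.169 with 1 array left out. That of subset effects between genotypes was 0.969, 0.969, 0.931 and 0.933 in the same order, and 0.922 to 0.951.

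Deviations from the group mean correlated at 0.534 between control and knockout CD80low arrays of equal replicate number and at 0.447 in CD80high cells, against 0.0776 to 0.131 between subsets. The labels give these arrays only a number in common, and the cause was not tested. A slide term was not run, since no label ties a slide to a sample.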

Other observations

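The tests that weigh explanations of the Slc13a2 pattern and the lists of mTEC subtypes were chosen after the results were seen, while the count over regroupings of the arrays was set beforehand. For an origin from the driver construct, the change of Foxn1 itself (-0.04) was tried first and was replaced by the gap between arrays after both values were known.

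Some mTECs take on programs of peripheral cell types, and lists for 6 such subtypes were compared in addition to the tuft and muscle lists. In CD80low knockouts neuroendocrine genes were lower in 4 of 5 cases (median -0.70, adjusted p = 9.63e-04, adjusted p = 0.11 with an estimated correlation), with the hormone granule gene Resp18 at -0.84. The other 5 lists were not called: enterocyte and hepatocyte (-0.35, adjusted p = 0.129), goblet (-0.10, 0.724), ciliated (-0.07, 0.607), ionocyte (-0.01, 0.647) and microfold genes (0.04, 0.724). In CD80high knockouts 4 of the 6 lists were lower: enterocyte and hepatocyte (-0.56, adjusted p = 1.38e-04, adjusted p = 0.0736 with an estimated correlation), ciliated (-0.23, 0.00134, 0.119 with an estimated correlation), neuroendocrine (-0.19, 0.0212, 0.119 with an estimated correlation) and goblet genes (-0.32, 0.0421, 0.159 with an estimated correlation). Ionocyte (-0.16, adjusted p = 0.0783) and microfold genes (-0.04, 0.0593) were not called there. These 6 lists held only 3 to 8 tested genes each. They were not run under the processing alternatives or with single arrays left out. The enterocyte and hepatocyte list shares Vil1, Reg3g and Apoa4 with the intestinal list, so its call is not separate from the intestinal one. The goblet list shares Tff3 with the intestinal and Aire-dependent lists, and the neuroendocrine list shares Resp18 with the Aire-independent list.

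Higher Slc13a2 in knockouts could come from activation of its whole neighbourhood around Foxn1, the transcription factor that drives TEC development, but the highest average change among tested neighbours was 0.18 (Spag5). Kidney or intestinal cells in the sorts would raise other genes of those tissues, and the higher of the 2 subsets' medians for kidney and brush border genes was -0.022. A Foxn1-based driver construct that carries Slc13a2, which lies next to Foxn1, stays open because the labels name no driver. The smaller gap between the lowest knockout and the highest control array, 4.82, restates the pattern and lends that explanation no weight. An effect of Hipk2 on Slc13a2, measured by 1 probe, stays open and untested.

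Among 34 splits of the 8 arrays into 4 and 4, 2 called at least as many genes as the genotype split, which itself called 1. The other was the split by replicate number, with 1 gene, Hspa1b, a heat shock gene named after the values were seen. The remaining 32 splits called 0, and the highest of the splits other than genotype was 1. The count does not exclude chance, but the split that equals it follows replicate number, along which the CD80low arrays part in both genotypes. The count also takes no account of the size of the Slc13a2 change (5.85 ± 0.165 SE).

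Single CD80low arrays held bright transcripts of rare kinds, in genes picked after their values were seen. Thyroglobulin (Tg) reached a log2 intensity of 11.66 in knockout CD80low replicate 2, 6.41 above the next CD80low array. Of the other 6 thyroid genes tested, Iyd (7.14, 1.41 above the next), Dio1 (8.68 against 8.50) and Slc5a5 (7.07 against 6.96) were also highest there, by less than 2, and Duoxa2, Foxe1 and Slc26a4 were not. Mucl2 (9.74), Mup5 (8.85) and Mup2 (8.19) were highest in knockout CD80low replicate 1, Upk3b (10.28) in control CD80low replicate 1 and Lce1c (7.76) in control CD80low replicate 2. In the CD80high arrays, 0 genes stood more than 2 above the other 3.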
